A study of Homo sapiens with 24 samples.

How the data were processed

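Total RNA of RPMI 2650 cells was labelled with biotin and hybridised to Illumina HumanHT-12 bead arrays, 24 arrays on 2 chips of 12 per the labels. Per the file headers, the deposited table of raw values holds for each array and probe a mean signal intensity over the beads, on a linear scale, and a detection p-value, the chance that a negative control bead is as bright as the probe. The intensities in it were neither background-corrected nor normalized, since the lowest was 73.8 and the arrays differed in their quantiles. The other deposited table holds intensity values processed by the authors with GenomeStudio, per the submitters' processing notes. From the values, these had been background-subtracted (the lowest per array lay between -20.7 and -19.0) and quantile-normalized over all 24 arrays. The version and settings of GenomeStudio and the build of the probe annotation are not given in the sources used here. The columns of the raw values were joined to the samples by the sample names in the labels. A further 48 columns, with bead numbers and bead standard errors, were not analysed here.

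Of 47231 probes, 30113 were listed with 1 gene each, 8 with several and 17110 with none, and 30074 of the single genes were in the RefSeq gene table used, where 0 symbols had changed. Raw intensities were background-corrected and quantile-normalized over the 24 arrays with neqc of limma 3.58.1 (offset 16, background estimated from the detection p-values) in R 4.3.3, with version 1.17.8 of data.table. A probe was kept when its detection p was under 0.05 on all 3 arrays of at least 1 of the 8 sets of arrays formed by group and chip, which 20073 probes met. Of these, 15584 had 1 gene, and each gene was represented by its probe with the highest mean, which gave 11751 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

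Groups followed the labels, and samples were not paired, except in an added fit of the unexposed cells. Those with the same number in their sample names on both chips (replicates 1 and 4, 2 and 5, 3 and 6) had correlations of deviations of 0.27, 0.29 and 0.56. Linear models with 1 mean per set (lmFit with 16 residual degrees of freedom, eBayes with 5.87 prior degrees of freedom) gave 12 comparisons: high and low fume against clean air and against each other at each time, clean air against unexposed cells on the same chip, the differences between the effects at 4 h and at 0 h, and the unexposed cells of the 2 chips against each other. Since time and chip coincide, no direct comparison of 4 h with 0 h was made, and a difference of effects removes a chip effect only where it is the same for both groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. All tests were two-sided.

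There were 20 gene lists: metallothioneins and metal response, NRF2 antioxidant, iron homeostasis, heat shock, endoplasmic reticulum unfolded protein response, ATF4 amino acid response, NF-kB inflammation, interferon-stimulated, p53 targets, immediate early, aryl hydrocarbon receptor, hypoxia and glycolysis, cell cycle, cholesterol biosynthesis, osmotic response, circadian clock, oxidative phosphorylation, apoptosis regulators, airway epithelial and mucin, and markers of other cell types. They were tested with camera (preset inter-gene correlation of 0.01, then an estimated one), adjusted over the lists of a comparison, and with fry. The lists, the comparisons, the tests, the named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The genes named were, for each comparison, up to 10 higher and up to 10 lower with the largest change among the called genes whose 3 arrays of one set all lay above or below the 3 of the other (for differences of effects, up to 5 each way). They also include, in every fume comparison, HMOX1, NQO1, MT2A, MT1X, TFRC, CXCL8, CDKN1A, HSPA1A, DDIT3 and CYP1A1. Called members of the fixed lists were added, of which the text names the 2 with the largest change in the direction of each called list, and all called members of the metal response list in the fume comparisons. Where fewer than 5 genes passed, the 5 with the smallest p are given.

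The alternatives were no background correction, scaling to the 75th percentile, normalization per chip, the authors' values, no filter on dim probes, probes detected on all arrays, all probes, the compared groups alone, array weights, a 1.5-fold minimum, an adjusted p under 0.01, a block for the replicate number, unexposed cells as the control, and leaving out each array. Further ones were chosen after seeing the data: clean air 0 h replicate 1 as the lone clean air array at 0 h, the gene lists without that replicate, the gene classes under both, the correlations under other settings, and a block for these pairs of unexposed arrays. In such fits a lone array was assumed to vary like the other sets. The pipeline was tested on simulated data with known changes. For high fume against clean air at 4 h it recovered 61.2%, 95.5% and 100% of 1.5-, 2- and 4-fold changes, with 9 false calls. For the differences of the high fume and clean air effects it recovered 23.9% and 16.4% of 1.5-fold and 67.2% and 71.6% of 2-fold changes.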

Results

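Gene expression was measured on 24 bead arrays in RPMI 2650 cells, a line from a squamous carcinoma of the human nasal septum. The cells had been exposed for 6 h to clean air or to welding fume at 85 µg/m3 (low fume) or 760 µg/m3 (high fume). They were collected at once (0 h) or after 4 h of further incubation. Each of these 6 groups had 3 arrays, and 6 arrays held cells kept unexposed. The 0 h groups and unexposed replicates 1 to 3 lay on 1 chip. The 4 h groups and unexposed replicates 4 to 6 lay on the other. The arrays thus formed 8 sets of 3, and groups were compared within a chip. Between 18763 and 20327 of the 47231 probes were detected per array (39.7% to 43.0%). The median intensity per array lay between 105 and 116, and 11751 genes were tested. The number of arrays limits the precision. The labels call the samples biological replicates, and the p-values measure the spread between them. Changes below are log2 fold changes ± SE, with 3 arrays in each set. For genes given among the largest changes between sets, all 3 arrays of one set lay above all 3 of the other.

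The unexposed arrays lay far from all arrays of the exposure system in the plot of principal components, and the fume arrays split by time. The 3 arrays labelled clean air 0 h did not lie together. Replicate 1 was nearest to a low fume 0 h array (root mean square difference of 0.302 on the log2 scale). It differed by 0.516 to 0.537 from replicates 2 and 3. Replicates 2 and 3 differed by 0.214 from each other and by 0.223 to 0.347 from the clean air arrays at 4 h. Within the other sets the differences ran from 0.21 to 0.342. Counts that use these arrays are therefore given also without replicate 1 and with replicate 1 as the lone clean air array at 0 h, and list calls where either ended them.

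**Figure D1:**
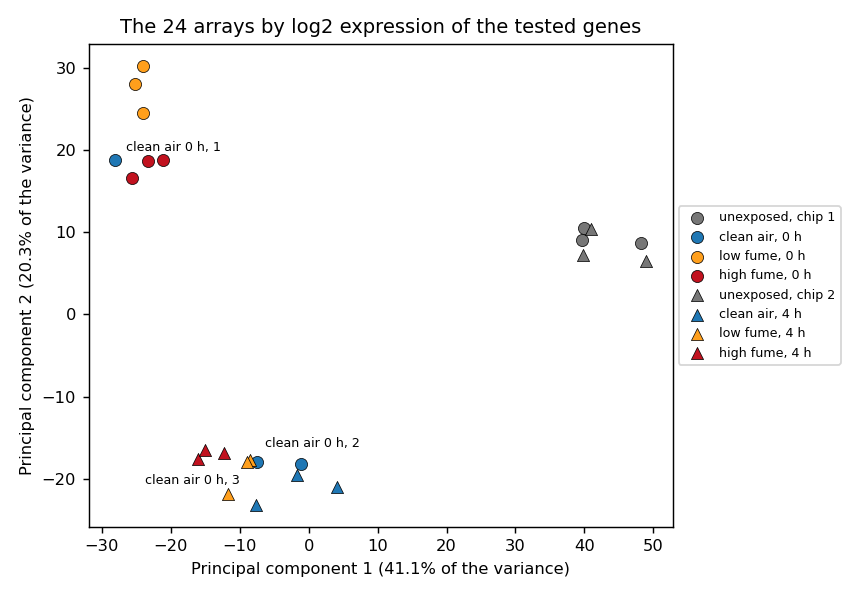
Each point is 1 of the 24 arrays at its values on the first and second principal components of log2 expression (unitless; 41.1% and 20.3% of the variance), coloured by group, with circles for the chip of the 0 h groups and triangles for that of the 4 h groups. Clean air 0 h replicate 1 sits at -28.1 and 18.9, among the fume arrays at 0 h, apart from replicates 2 and 3.

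High fume against clean air at 0 h asked what the higher concentration had changed by the end of the exposure. Genes of cell division rose. RRM2, a subunit of ribonucleotide reductase, which makes the building blocks of DNA, rose by 1.90 ± 0.16. The centromere protein gene CENPU rose by 1.80 ± 0.12, the histone chaperone gene ASF1B by 1.78 ± 0.19 and the proliferation marker MKI67 by 1.63 ± 0.19. In the cell cycle list 31 of 33 measured members were higher and 0 were lower (31 higher adjusted over the list alone), with a median of 1.01. Camera gave the list an adjusted p = 3.16e-22 (0.163 with an estimated correlation, marked estimated hereafter). The genes with the largest rises included RNAs of the spliceosome. RNU6ATAC and RNU11 of the minor spliceosome rose by 3.23 ± 0.43 and 2.12 ± 0.50. The U1 genes RNVU1-7, RNU1-1, RNU1-3 and RNVU1-18 rose by 2.76, 2.73, 2.70 and 2.45. Without clean air replicate 1 these 6 rises were 2.99 to 3.96. With it as the lone clean air array RNU6ATAC rose by 1.75 (adjusted p = 0.00742), and the other 5 stood at 0.38 to 0.94 and did not pass (adjusted p from 0.0663 to 0.626). The U3 small nucleolar RNA gene SNORD3D rose by 2.14 ± 0.35 (0.95 with that array alone, adjusted p = 0.0476).

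CAMKV, which encodes a kinase-like protein of vesicles, fell by 2.51 ± 0.30 in the same comparison. ESRRG, an orphan nuclear receptor, fell by 1.89 ± 0.17, the Wnt antagonist DKK1 by 1.76 ± 0.18 and the inducible heat shock gene HSPA6 by 1.64 ± 0.18 (detected on 1 of 3 high fume arrays). MIR124-2HG fell by 1.88, DIRC3 by 1.77 (detected on 1 of 3 high fume arrays) and the small nucleolar RNA gene SNORA25 by 1.76. The semaphorin gene SEMA3E fell by 1.66 and the bicarbonate transporter gene SLC4A7 by 1.64. With replicate 1 as the lone clean air array SEMA3E (-1.33, adjusted p = 0.12) and SNORA25 (-0.96, adjusted p = 0.105) did not pass. P2RX2, an ATP-gated channel, was not well above background with high fume and was at least 2.90-fold lower. Such bounds set the mean of the set with the gene detected against the lowest signal that each array of the other set detected. Across the other genes with the largest changes, the SE lay between 0.118 and 0.499 and the adjusted p was at most 0.00385.

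Stress genes fixed for all fume comparisons moved in different directions with high fume at 0 h. The cell cycle inhibitor gene CDKN1A rose by 0.70 ± 0.10 (adjusted p = 4.45e-05). The heat shock gene HSPA1A fell by 0.68 ± 0.15 (adjusted p = 0.00177) and the stress transcription factor gene DDIT3 by 0.84 ± 0.23 (adjusted p = 0.00715). The quinone reductase gene NQO1 fell by 0.38 ± 0.12 (adjusted p = 0.0183). HMOX1, heme oxygenase, had a change of 0.33 ± 0.27 (adjusted p = 0.385), and the chemokine gene CXCL8 one of 0.03 ± 0.19 (adjusted p = 0.916). The metallothionein genes MT2A (-0.03 ± 0.23, adjusted p = 0.937) and MT1X (0.47 ± 0.20, adjusted p = 0.0836) did not pass either. The transferrin receptor gene TFRC stood at -0.24 ± 0.10 (adjusted p = 0.0836). CYP1A1 was not detected well enough to be tested. NQO1 lost its call without clean air replicate 2 or high fume replicate 1 (adjusted p = 0.144 and 0.0514). Without clean air replicate 1, MT1X (0.82, adjusted p = 0.000161) and TFRC (-0.35, adjusted p = 0.00661) passed, and DDIT3 stood at -0.46 (adjusted p = 0.0419). With it alone NQO1 (-0.14, adjusted p = 0.511) and HSPA1A (-0.61, adjusted p = 0.0531) did not pass.

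In the metallothionein and metal response list 1 of 8 members was higher with high fume at 0 h and 3 were lower (2 and 3 adjusted over the list alone). The list as a whole was not called (camera adjusted p = 0.863). The zinc exporter gene SLC30A1 rose by 1.14 ± 0.33. The zinc importer gene SLC39A10 fell by 1.16 ± 0.31, MT1E by 0.75 ± 0.25 and MT1F by 0.36 ± 0.13. Single arrays decided these calls. SLC30A1 did not pass without clean air replicate 2 or 3 (adjusted p = 0.1 and 0.0662), reached 1.82 without replicate 1, and turned to -0.22 with it alone. SLC39A10 did not pass without clean air replicate 2 (-0.83, adjusted p = 0.0539) or with replicate 1 alone (-0.01). MT1F and MT1E did not pass without any 1 of 4 and 3 arrays (adjusted p from 0.0686 to 0.262).

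In all, limma called 3667 genes between high fume and clean air at 0 h, 1786 higher and 1881 lower (2261 and 1639 with 75th percentile scaling). The count was 4779 without clean air replicate 1, 2777 without clean air replicate 3 and 2479 with replicate 1 as the lone clean air array. It was 2088 with the compared groups alone.

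**Figure D2:**
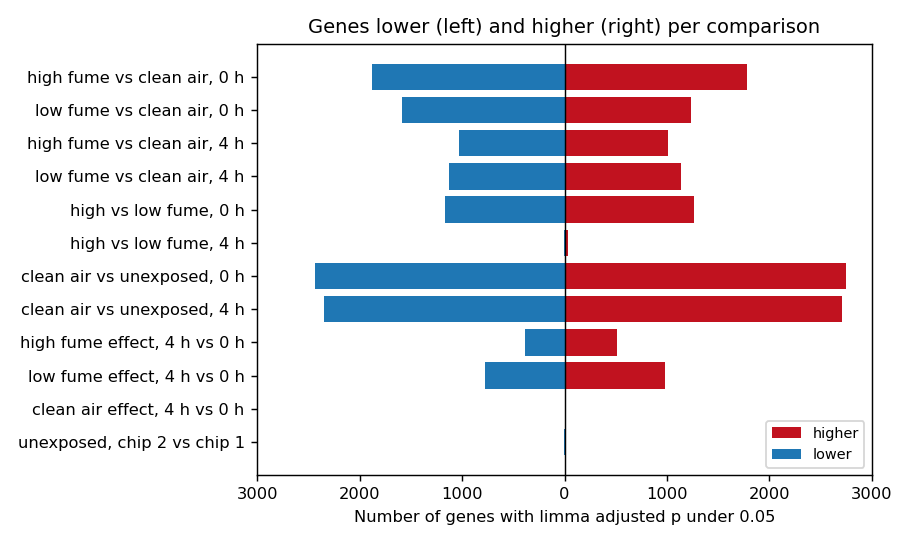
Bars show the number of genes called by limma in each of the 12 comparisons, split into higher and lower. The counts run from 0 for the difference between the clean air effects at 4 h and at 0 h to 5188 for clean air against unexposed cells at 0 h.

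Low fume against clean air at 0 h asked the same of the lower concentration. TENT5A, a nucleotidyltransferase gene, rose by 1.74 ± 0.36 and the transcription factor gene BHLHE40 by 1.68 ± 0.33. The glycogen-targeting phosphatase subunit gene PPP1R3C rose by 1.59 ± 0.31, the deiodinase gene DIO2 by 1.47 ± 0.21, and CD14, a co-receptor for bacterial lipopolysaccharide, by 1.42 ± 0.24. SPOCK1 rose by 1.47 and IMMP2L by 1.44. The cathelicidin gene CAMP rose by 1.69 ± 0.27 and PRND by 1.57 ± 0.31, each detected on 1 of 3 clean air arrays. PLAAT4 rose by 1.41 ± 0.18 (detected on 2 of 3). CAMKV fell by 2.21 ± 0.30 and the caveolin gene CAV1 by 1.80 ± 0.30 (detected on 2 of 3 low fume arrays). ANKRA2 fell by 1.78, ZMYM6 by 1.61, SLC4A7 by 1.51, ZNF680 by 1.46, FAM200C by 1.46, C1orf74 by 1.45 and DUS2 by 1.34. WDR33 fell by 1.69, but 1 of its 5 other probes was called in the opposite direction. The SE of these 20 changes lay between 0.179 and 0.358, and their adjusted p was at most 0.00272. With replicate 1 as the lone clean air array all 20 lost their calls (changes of 0.14 to 1.22 in size, adjusted p from 0.0518 to 0.714).

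A pair of stress lists were called higher with low fume at 0 h. In the ATF4 amino acid response list 8 of 21 members were higher and 1 was lower (8 and 1 adjusted over the list alone), with a median of 0.29. In the immediate early list 10 of 25 were higher and 1 was lower (10 and 1 adjusted over the list alone), with a median of 0.43. Each had a camera adjusted p = 0.034 (0.754 estimated). Clean air 0 h replicate 1 moved with both lists. Without it their camera adjusted p was 1.92e-06 and 7.05e-05, and with it as the lone clean air array both lists pointed down (0.0017 and 0.0821).

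In the ATF4 list the secreted glycoprotein gene STC2 rose by 1.88 ± 0.51 (adjusted p = 0.0116) and the mTOR inhibitor gene DDIT4 by 1.51 ± 0.39 (adjusted p = 0.00892). STC2 and DDIT4 did not pass without clean air replicate 2 or 3 (adjusted p from 0.0852 to 0.114), and stood at 3.03 and 2.39 without replicate 1. In the immediate early list FOSB rose by 1.28 ± 0.30 (0.83 without clean air replicate 2) and NR4A2 by 1.24 ± 0.39 (adjusted p = 0.0241). NR4A2 did not pass without any 1 of 4 arrays (adjusted p from 0.053 to 0.207), and stood at 1.95 without clean air replicate 1. With that array as the lone clean air array STC2 (-0.42), DDIT4 (-0.26) and NR4A2 (-0.18) changed direction and FOSB stood at 0.19 (adjusted p = 0.756).

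TFRC fell by 0.43 ± 0.10 (adjusted p = 0.00637) and HSPA1A by 0.44 ± 0.15 (adjusted p = 0.0409) with low fume at 0 h, and MT1X rose by 0.57 ± 0.20 (adjusted p = 0.0429). HMOX1 (0.74 ± 0.27, adjusted p = 0.0526), NQO1 (-0.05 ± 0.12), MT2A (0.15 ± 0.23), CXCL8 (-0.20 ± 0.19), CDKN1A (0.12 ± 0.10) and DDIT3 (0.00 ± 0.23) did not pass. In the metal response list 2 of 8 members were higher and 1 was lower (2 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.728). Besides MT1X these were SLC30A1 (0.98 ± 0.33) and SLC39A10 (-1.14 ± 0.31). TFRC did not pass without clean air replicate 2 (-0.33, adjusted p = 0.0615). SLC39A10 lost its call without any 1 of 3 arrays, and MT1X, SLC30A1 and HSPA1A without any 1 of 5 (adjusted p from 0.0571 to 0.276). Without clean air replicate 1 SLC30A1 stood at 1.66, SLC39A10 at -1.71 and MT1X at 0.93, and with it alone they changed direction (-0.39, 0.02 and -0.14), and TFRC and HSPA1A did not pass (adjusted p = 0.48 and 0.466). HMOX1 passed without that array or low fume replicate 2 (adjusted p = 0.0143 and 0.0201).

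limma called 2822 genes for low fume at 0 h, 1232 higher and 1590 lower. This count rested on the arrays labelled clean air 0 h. It was 4705 without replicate 1, 995 without replicate 2, 1128 without replicate 3, and 5 with replicate 1 as the lone clean air array. It was 1671 without low fume replicate 2 and 1878 without low fume replicate 3. When the arrays of the compared groups alone entered the limma fit it was 0, against 4353 genes at an unadjusted p under 0.05 in the fit of all arrays.

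High fume against low fume at 0 h used none of the clean air arrays and asked how the concentrations differed. Genes of DNA synthesis and mitosis were higher with high fume. RRM2 rose by 1.92 ± 0.16, the mitotic kinesin gene KIF20A by 1.66 ± 0.20, the spindle gene DLGAP5 by 1.63 ± 0.22, cyclin A2 (CCNA2) by 1.61 ± 0.23 and the kinase gene AURKB by 1.60 ± 0.22. The DNA glycosylase gene NEIL3 rose by 1.63, the histone gene H2BC9 by 1.66 and SAPCD2 by 1.86 (detected on 2 of 3 low fume arrays). The cell cycle list had 31 of 33 members higher and 0 lower (32 higher and 1 lower adjusted over the list alone), with a median of 1.15. Its camera adjusted p = 1.11e-30 (0.0525 estimated). The small Cajal body RNA gene SCARNA23 rose by 1.80 ± 0.17 (detected on 1 of 3 low fume arrays). SCARNA8, not well above background with low fume, was at least 3.27-fold higher.

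DIO2 fell by 2.35 ± 0.21 from low to high fume at 0 h, and KCNIP4 by 2.20 ± 0.34 and PRND by 1.85 ± 0.31 (both detected on 1 of 3 high fume arrays). The leptin receptor gene LEPR fell by 1.75 ± 0.26, the Wnt ligand gene WNT5A by 1.70 ± 0.32 and the growth factor binding protein gene IGFBP5 by 1.65 ± 0.16. ZCCHC12 fell by 1.74, DIRC3 by 1.63 (detected on 1 of 3 high fume arrays), NPW by 1.60 and SHROOM4 by 1.59. The adjusted p of the genes with the largest changes was at most 0.00389. limma called 2433 genes in all, 1268 higher and 1165 lower with high fume.

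The ATF4 list was lower with high than with low fume at 0 h, with 8 of 21 members lower and 0 higher (11 lower adjusted over the list alone) and a median of -0.47. The camera adjusted p of this list was 0.00187 (0.598 estimated). DDIT3 fell by 0.84 ± 0.23 (adjusted p = 0.0112), the glutathione-degrading enzyme gene CHAC1 by 1.11 ± 0.31 (adjusted p = 0.0147) and DDIT4 by 1.10 ± 0.39 (adjusted p = 0.049). The p53 list was higher, with 6 of 22 members higher and 0 lower (6 higher adjusted over the list alone) and a median of 0.20. For these genes camera gave an adjusted p = 0.0129 (0.598 estimated). CDKN1A rose by 0.58 ± 0.10 (adjusted p = 0.000391), the DNA damage binding gene DDB2 by 0.76 ± 0.17 (adjusted p = 0.003) and the death receptor gene FAS by 0.67 ± 0.18 (adjusted p = 0.00976, detected on 2 of 3 low fume arrays). DDIT4 did not pass without any 1 of the 6 arrays (adjusted p from 0.0806 to 0.134). CHAC1 did not pass without high fume replicate 1 (-1.05, adjusted p = 0.0541), nor FAS without that array or low fume replicate 3 (adjusted p = 0.0569 and 0.0578).

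NQO1 fell by 0.33 ± 0.12 (adjusted p = 0.0489) from low to high fume at 0 h. MT1E fell by 0.83 ± 0.25 (adjusted p = 0.0235) as the 1 called member of the metal response list (1 adjusted over the list alone), which was not called (camera adjusted p = 0.52). HMOX1 (-0.41 ± 0.27), MT2A (-0.18 ± 0.23), MT1X (-0.11 ± 0.20), TFRC (0.19 ± 0.10), CXCL8 (0.23 ± 0.19) and HSPA1A (-0.25 ± 0.15) did not pass. Leaving out any 1 of the 6 arrays ended the call of NQO1 (adjusted p from 0.057 to 0.153). MT1E did not pass without any 1 of 4 arrays (adjusted p from 0.0602 to 0.0953).

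High fume against clean air at 4 h asked which changes were seen after further incubation. The spliceosomal RNAs RNU6ATAC (3.36 ± 0.43), RNU1-1 (3.29 ± 0.48), RNU1-3 (3.15), RNVU1-7 (3.14), RNVU1-18 (2.88) and RNU11 (2.65 ± 0.50) rose. The histone gene H2BC26 rose by 2.43 ± 0.20 (detected on 1 of 3 clean air arrays), the immediate early transcription factor gene EGR1 by 2.26 ± 0.24 and TRIM16L by 2.05 ± 0.38. DPF3, not well above background in clean air, was at least 3.07-fold higher. C21orf58 fell by 2.26 ± 0.32, the meiotic recombinase gene DMC1 by 2.19 ± 0.36, CAMKV by 2.16 ± 0.30 and the actin-binding protein gene TAGLN by 2.04 ± 0.15. SNORA25 fell by 2.16, MCMDC2 by 2.14, SHROOM4 by 2.08, the RNA helicase gene DDX51 by 2.05, ABRAXAS1 by 2.04 and TMEM17 by 2.04. The adjusted p of these genes was at most 0.00084. limma called 2042 genes, 1009 higher and 1033 lower. The count was 1150 without clean air replicate 1 and 1233 without high fume replicate 3.

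Sterol synthesis genes fell with high fume at 4 h, with 10 of 18 members of the cholesterol list lower and 0 higher (11 lower adjusted over the list alone) and a median of -0.53. The list had a camera adjusted p = 2.65e-07 (0.165 estimated). HSD17B7 fell by 1.79 ± 0.30 and ACAT2 by 0.93 ± 0.18. The immediate early list had 8 of 25 members higher and 0 lower (11 higher adjusted over the list alone), with a median of 0.40 and a camera adjusted p = 0.000158 (0.52 estimated). NR4A2 in it rose by 1.27 ± 0.39 (adjusted p = 0.0271). Of the genes of the endoplasmic reticulum unfolded protein response, 5 of 16 were higher and 0 lower (7 higher adjusted over the list alone), with a median of 0.22. Camera gave an adjusted p = 0.00615 (0.52 estimated). SDF2L1 rose by 1.06 ± 0.13 and the chaperone gene HSPA5 by 0.88 ± 0.18. NR4A2 did not pass without any 1 of 4 arrays (adjusted p from 0.0735 to 0.0931).

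The ATF4 list had 4 of 21 members higher with high fume at 4 h and 0 lower (4 higher adjusted over the list alone), with a median of 0.35. Its camera adjusted p was 0.0177 (0.696 estimated). STC2 rose by 1.49 ± 0.51 (adjusted p = 0.047), and CHAC1, not well above background in clean air, was at least 2.03-fold higher. The NRF2 antioxidant list had 5 of 20 members higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.22. With camera its adjusted p was 0.0356 (0.167 estimated), and 0.0522 without clean air 0 h replicate 1 in the fit, and the call ended as well with it as the lone clean air array. GCLC, which makes the first step of glutathione synthesis, rose by 0.57 ± 0.14, and transketolase, TKT, by 0.56 ± 0.15. STC2 did not pass without any 1 of the 6 arrays (adjusted p from 0.0827 to 0.131). GCLC did not pass without clean air replicate 1, nor TKT without it or high fume replicate 2 (adjusted p from 0.0583 to 0.0998).

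NQO1 fell by 0.42 ± 0.12 (adjusted p = 0.0162) and CXCL8 by 0.71 ± 0.19 (adjusted p = 0.0131, detected on 2 of 3 high fume arrays) with high fume at 4 h. CDKN1A rose by 0.31 ± 0.10 (adjusted p = 0.0422). HMOX1 (0.13 ± 0.27), MT2A (0.44 ± 0.23), MT1X (0.19 ± 0.20), TFRC (-0.07 ± 0.10), HSPA1A (-0.41 ± 0.15) and DDIT3 (0.52 ± 0.23) did not pass. In the metal response list limma called 0 of 8 members, over all genes or adjusted over the list alone (camera adjusted p = 0.747), against 3606 of all genes at an unadjusted p under 0.05. CDKN1A did not pass without any array except clean air replicate 3 (adjusted p from 0.09 to 0.17). CXCL8 and NQO1 each did not pass without any 1 of 3 arrays (adjusted p from 0.0504 to 0.082). HSPA1A passed without clean air replicate 1 (-0.54, adjusted p = 0.0379).

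**Figure D3:**
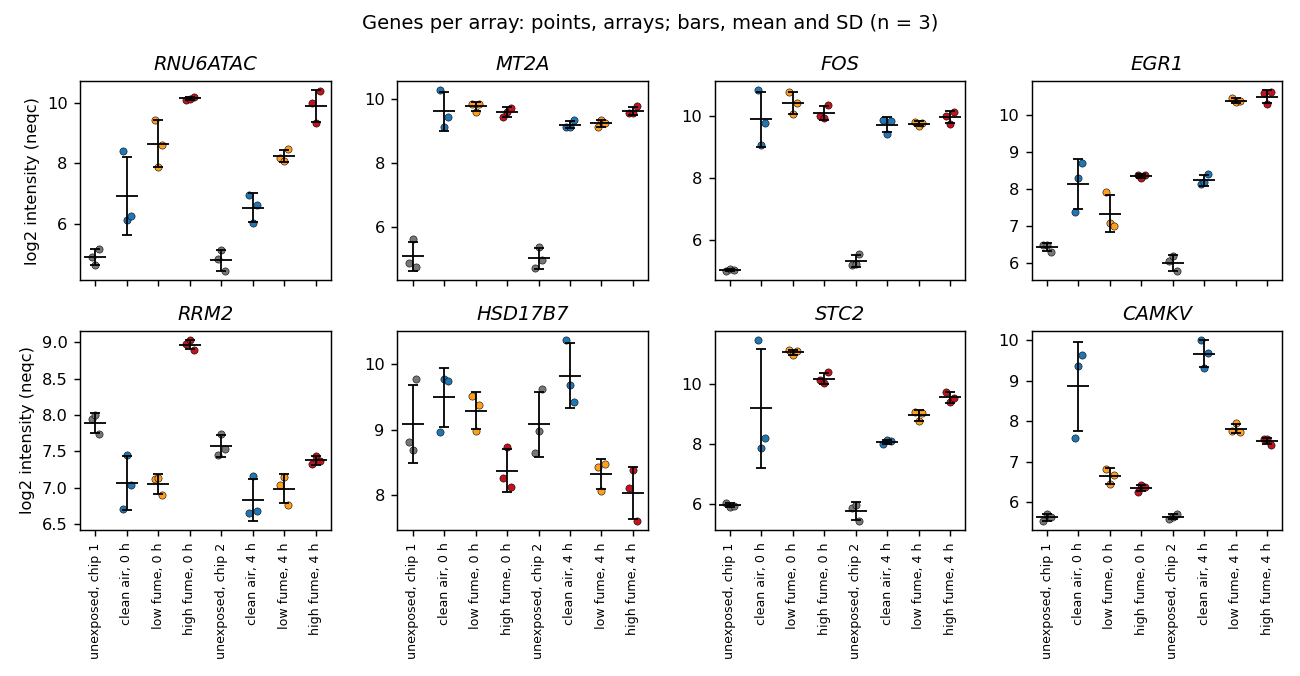
Each panel plots the log2 expression of 1 gene on each array (points) by set, with the mean and SD of the 3 arrays of a set (bars). RNU6ATAC stands at a mean of 10.1 with high fume at 0 h and at 6.92 in the arrays labelled clean air 0 h, and MT2A and FOS are higher in all exposure groups than in unexposed cells.

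Low fume against clean air at 4 h asked the same of the lower concentration. EGR1 rose by 2.15 ± 0.24, the stress gene GADD45G by 2.03 ± 0.26, the binding protein gene IGFBP4 by 1.74 ± 0.22 and the neurofilament gene NEFH by 1.72 ± 0.18. RNU1-3 rose by 2.05 ± 0.47, RNU1-1 by 1.96, RNVU1-7 by 1.95, RNVU1-18 by 1.90 and RNU6ATAC by 1.71 ± 0.43. CAMP, not well above background in clean air, was at least 2.94-fold higher. C21orf58 fell by 2.13 ± 0.32, the lysosomal membrane protein gene LAMP5 by 1.91 ± 0.11, CAMKV by 1.85 ± 0.30 and TAGLN by 1.83 ± 0.15. DMC1 fell by 2.09, PAXIP1-DT by 1.88, AOC4P by 1.86, COA8 by 1.84, SHISA3 by 1.82 and ARL16 by 1.82. The adjusted p of these genes was at most 0.0084. limma called 2265 genes, 1139 higher and 1126 lower. The count was 1101 without clean air replicate 1 and 1423 without low fume replicate 1.

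The cholesterol list fell with low fume at 4 h, with 8 of 18 members lower and 0 higher (9 lower adjusted over the list alone) and a median of -0.49. Its camera adjusted p was 7.19e-06 (0.197 estimated). HSD17B7 fell by 1.5 ± 0.30 and HMGCS1 by 1.08 ± 0.12. The endoplasmic reticulum list had 5 of 16 members higher and 0 lower (8 higher adjusted over the list alone), with a median of 0.32 and a camera adjusted p = 0.00682 (0.619 estimated). SDF2L1 rose by 1.03 ± 0.13 and HSPA5 by 0.68 ± 0.18 (adjusted p = 0.0125). The heat shock list had 6 of 20 members higher and 0 lower (7 higher adjusted over the list alone), with a median of 0.26 and a camera adjusted p = 0.00978 (0.619 estimated). The chaperone gene HSPA8 rose by 0.70 ± 0.11 and the co-chaperone gene STIP1 by 0.66 ± 0.11. HSPA5 did not pass without clean air replicate 1 or low fume replicate 1 (adjusted p = 0.0842 and 0.0584).

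NQO1 fell by 0.51 ± 0.12 (adjusted p = 0.00477) and CDKN1A rose by 0.36 ± 0.10 (adjusted p = 0.0194) with low fume at 4 h. MT1E fell by 0.86 ± 0.25 (adjusted p = 0.0204) as the 1 called member of the metal response list (1 adjusted over the list alone), which was not called (camera adjusted p = 0.617). HMOX1 (-0.40 ± 0.27), MT2A (0.04 ± 0.23), MT1X (-0.02 ± 0.20), TFRC (0.14 ± 0.10), CXCL8 (-0.21 ± 0.19), HSPA1A (0.16 ± 0.15) and DDIT3 (0.30 ± 0.23) did not pass. CDKN1A and MT1E lost their calls without any 1 of 4 and 3 arrays (adjusted p from 0.052 to 0.0975).

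High fume against low fume at 4 h asked whether the concentrations still differed. ARL14 rose by 1.83 ± 0.28, the tight junction gene CLDN1 by 1.49 ± 0.18 (adjusted p = 0.000174), the histone genes H2BC26 and H4C5 by 1.16 ± 0.20 and 1.13 ± 0.18, and the metalloproteinase gene MMP10 by 1.08 ± 0.16. DPF3 rose by 1.28, SCARNA11 by 1.13, the GTPase gene GEM by 1.07, SERTAD4-AS1 by 1.02 and the p53 target PMAIP1 by 0.71 ± 0.16. The linker histone gene H1-4, not well above background with low fume, was at least 2.18-fold higher (adjusted p = 1.14e-05). ITM2A fell by 0.75 ± 0.13, HM13 by 0.65, the peptide gene GRP by 0.64 ± 0.14, ANKHD1-EIF4EBP3 by 0.55 and PCOLCE2 by 0.55. limma called 40 genes, 35 higher and 5 lower with high fume, against 1435 at an unadjusted p under 0.05. Of the 16 named, CLDN1 and H1-4 passed without any 1 array. Leaving out replicates 1, 2 and 3 of high fume ended 12, 6 and 14 calls, and of low fume 10, 9 and 10 (adjusted p from 0.0524 to 0.325). The count was 2 without high fume replicate 3, at most 15 without 4 others, and higher with array weights or these groups alone.

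None of the genes fixed for all fume comparisons passed between the concentrations at 4 h. Their changes were 0.53 ± 0.27 for HMOX1, 0.08 ± 0.12 for NQO1, 0.40 ± 0.23 for MT2A, 0.22 ± 0.20 for MT1X and -0.21 ± 0.10 for TFRC. They were -0.50 ± 0.19 for CXCL8 (detected on 2 of 3 high fume arrays), -0.05 ± 0.10 for CDKN1A, -0.58 ± 0.15 for HSPA1A (adjusted p = 0.0948) and 0.22 ± 0.23 for DDIT3. A few lists were called by camera although limma called 0 of their members over all genes. The immediate early list was higher (7 higher adjusted over the list alone), with an adjusted p = 3.22e-08 (0.521 estimated). The heat shock list was lower (5 lower adjusted over the list alone), with an adjusted p = 4.91e-05 (0.521 estimated). The cell cycle list was higher (0 adjusted over the list alone), with an adjusted p = 0.00113 (0.782 estimated). The ATF4 list was higher (2 higher adjusted over the list alone), with an adjusted p = 0.00166 (0.782 estimated). The metal response list had 0 of 8 members called (0 adjusted over the list alone, camera adjusted p = 0.278).

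Clean air against unexposed cells asked what the exposure system itself changed. FOS, an immediate early transcription factor gene, rose by 4.88 ± 0.27 at 0 h and by 4.41 ± 0.27 at 4 h. FOSB rose by 3.79 ± 0.30 and 3.62 ± 0.30 (detected on 1 of 3 unexposed arrays of the 4 h chip). The metallothionein genes MT2A (4.52 ± 0.23 and 4.17 ± 0.23, detected on 2 of 3 unexposed arrays of each chip) and MT1F (3.71 ± 0.13 and 3.53 ± 0.13) rose. MT1H was at least 12.1-fold higher at 0 h, where unexposed cells were not well above background. At 4 h it rose by 3.33 ± 0.19 (detected on 1 of 3 unexposed arrays). The motor protein gene KIF1A rose by 3.70 and 3.25, TAGLN by 3.60 and 3.60, REEP1 by 3.58 and 3.69, the TWEAK receptor gene TNFRSF12A by 3.29 and 3.41, and CAMKV by 3.23 and 4.02. FGFR3, a growth factor receptor gene, fell by 2.42 ± 0.17 at 0 h and by 2.65 ± 0.17 at 4 h, FGGY by 1.84 and 2.23, and P2RY14 by 1.74 and 1.86.

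At 0 h the DNA primase gene PRIM1 fell by 1.94, MMP11 by 1.88, APOBEC3F by 1.77, NFE2 by 1.76, MAMSTR by 1.71, C12orf56 by 1.68 and PLAAT4 by 1.66 (detected on 2 of 3 clean air arrays). At 4 h SLCO2A1 fell by 2.29, ACOX2 by 1.96, SLC39A11 by 1.92, GPR162 by 1.90, the oxytocin receptor gene OXTR by 1.89, C14orf93 by 1.87 and CTCFL by 1.85. The adjusted p of all these genes was at most 1.89e-05. limma called 5188 genes at 0 h, 2751 higher and 2437 lower. It called 5052 at 4 h, 2707 higher and 2345 lower. The count at 0 h was 5159 without clean air replicate 1 and 5002 with that replicate as the lone clean air array. It was 3010 with the compared groups alone.

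Lists of stress genes were higher in clean air than in unexposed cells at 0 h and at 4 h. The metal response list had 7 of 8 members higher and 0 lower at each time (7 higher and 1 lower, and 7 higher, adjusted over the list alone), with medians of 1.57 and 1.21. By camera the adjusted p was 4.31e-06 and 2.29e-05 (0.132 and 0.256 estimated). The immediate early list had 20 and 19 of 25 members higher (20 and 19 adjusted over the list alone). Camera gave it an adjusted p = 4.31e-11 and 2.33e-07 (0.132 and 0.293 estimated). The ATF4 list had 17 of 21 members higher at 0 h, and 13 higher and 1 lower at 4 h (17, and 14 and 1, adjusted over the list alone). For it camera gave an adjusted p = 4.6e-07 and 0.000757 (0.204 and 0.344 estimated). STC2 rose by 3.22 ± 0.51 and 2.30 ± 0.51 and ATF3 by 2.71 ± 0.35 and 2.09 ± 0.35. STC2 stood at 2.08 at 0 h without clean air replicate 1.

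The heat shock list had 16 of 20 members higher in clean air and 1 lower at 0 h, and 13 higher and 2 lower at 4 h (17 and 1, and 13 and 2, adjusted over the list alone). Its adjusted p by camera was 0.000261 and 0.00435 (0.204 and 0.344 estimated). HSPA6 rose by 1.87 ± 0.18 (detected on 1 of 3 unexposed arrays) and 1.80 ± 0.18, and the co-chaperone gene BAG3 by 1.72 and 1.57. The NF-kB list had 8 of 13 higher and 2 lower at 0 h, and 7 higher and 2 lower at 4 h (9 and 2, and 7 and 2, adjusted over the list alone). Its adjusted p by camera was 0.0182 and 0.0388 (0.132 and 0.293 estimated). The chemokine gene CCL20 rose by 1.98 ± 0.21 at 0 h (detected on 2 of 3 unexposed arrays). At 4 h, where unexposed cells were not well above background, it was at least 5.16-fold higher. NFKBIZ rose by 1.36 and 1.54.

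The p53 list had 10 of 22 members higher in clean air and 2 lower at 0 h, and 13 higher and 2 lower at 4 h (10 and 2, and 13 and 2, adjusted over the list alone). Camera gave an adjusted p = 0.0386 and 0.00435 (0.355 and 0.293 estimated). GADD45A rose by 1.66 and 1.82 and CDKN1A by 1.07 and 1.04. The hypoxia and glycolysis list had 15 of 26 higher and 1 lower at 0 h, and 14 higher and 1 lower at 4 h (17 and 1, and 15 and 1, adjusted over the list alone). Its camera adjusted p was 0.000307 and 0.00435 (0.176 and 0.293 estimated). The glycolytic genes PFKFB3 and HK2 rose by 1.32 and 1.27 at 0 h and by 1.06 and 0.98 at 4 h. The cholesterol list had 11 of 18 higher at 0 h, and 10 higher and 1 lower at 4 h (11, and 11 and 1, adjusted over the list alone). It had a camera adjusted p = 0.00105 and 0.000757 (0.204 and 0.293 estimated). HMGCS1 rose by 1.54 and 1.58, DHCR7 by 1.30 at 0 h and INSIG1 by 1.58 at 4 h. With replicate 1 as the lone clean air array at 0 h the p53 and cholesterol calls ended there (camera adjusted p = 0.634 and 0.101).

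A pair of lists were lower in clean air than in unexposed cells. The cell cycle list had 14 of 33 lower and 1 higher at 0 h, and 13 lower at 4 h (15 and 1, and 13, adjusted over the list alone). Camera called this list with an adjusted p = 0.000469 and 0.000757 (0.355 and 0.426 estimated). KIF20A fell by 1.06 and 1.13, CCNB2 by 0.999 at 0 h and MCM5 by 1.08 at 4 h. The oxidative phosphorylation list had 13 of 19 lower at 0 h, and 8 lower and 1 higher at 4 h (14, and 8 and 1, adjusted over the list alone). For this list camera gave an adjusted p = 0.000822 and 0.0159 (0.132 and 0.293 estimated). The respiratory complex III genes UQCRC2 and UQCRC1 fell by 0.84 and 0.80 at 0 h and by 0.76 and 0.72 at 4 h.

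**Figure D4:**
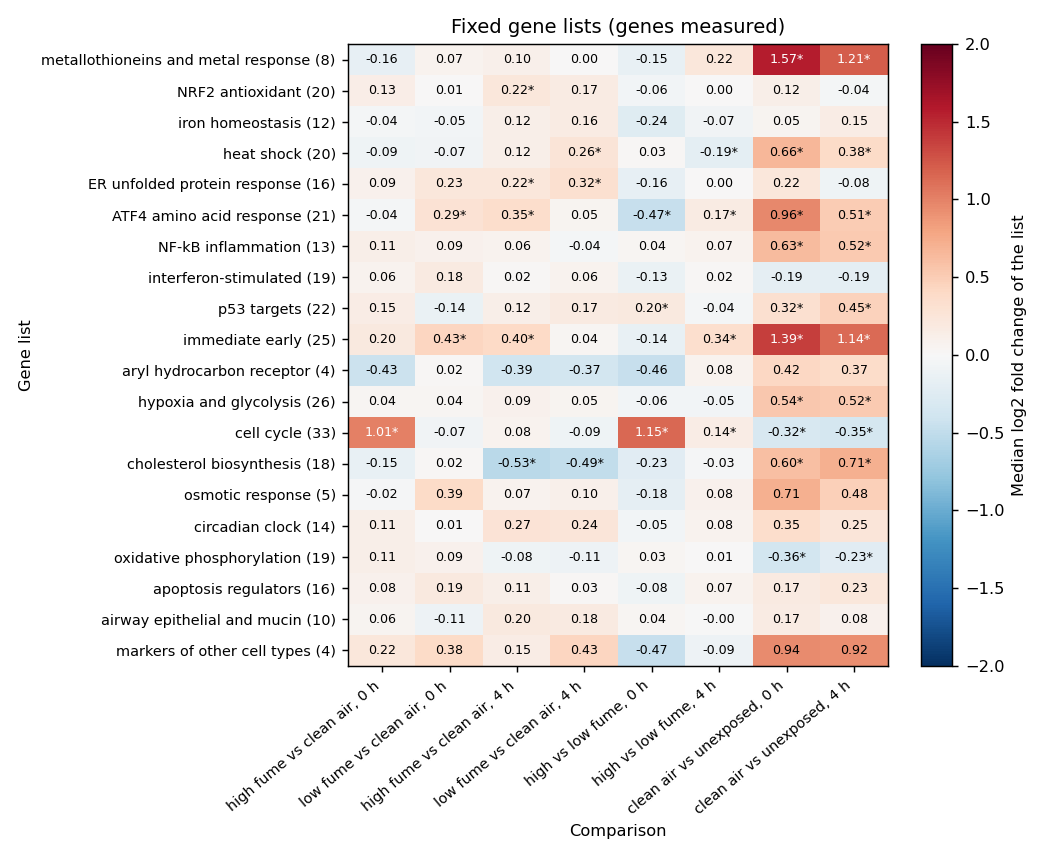
Each cell is the median log2 fold change of the measured members of a fixed gene list (vertical axis) in 1 of the 8 comparisons of 2 sets (horizontal axis), with a star where camera gave an adjusted p under 0.05 with its preset correlation. The cell cycle list has medians of 1.01 and 1.15 for high fume at 0 h against clean air and against low fume, and the metal response list has medians of 1.57 and 1.21 for clean air against unexposed cells.

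The difference between the high fume effects at 4 h and at 0 h tested which responses depended on time. The cell division genes LIG1 (-1.72 ± 0.17), PLK1 (-1.68), AURKB (-1.67), TACC3 (-1.66) and ZWINT (-1.57) had a lower effect at 4 h. ARL14 (2.86 ± 0.39 as fitted), EGR1 (2.04 ± 0.33), H2BC26 (1.93, detected on 1 of 3 clean air arrays at each time), KLHL24 (1.87), ENPP5 (1.80) and DDIT3 (1.36 ± 0.32) had a higher one. ARL14 was not detected with high fume at 0 h (2 of 3 clean air arrays), and its difference was 2.41 with that set at its lowest detected signals. The cell cycle list had 22 of 33 members lower and 0 higher (26 lower adjusted over the list alone), with a median of -0.95. Its camera adjusted p was 5.3e-24 (0.127 estimated). In the cholesterol list 3 of 18 members were lower (4 adjusted over the list alone), with a camera adjusted p = 0.00021 (0.256 estimated). The ATF4 list was called higher with 1 of 21 members, DDIT3 (1 adjusted over the list alone), with a camera adjusted p = 0.00419 (0.688 estimated). This call ended without clean air 0 h replicate 1 (camera adjusted p = 0.589). The oxidative phosphorylation list was called lower by camera with 0 members called by limma, over all genes or adjusted over the list alone (adjusted p = 0.00337, and 0.256 estimated). Over all genes, 2731 had an unadjusted p under 0.05.

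Of the fixed genes, HMOX1 (-0.20 ± 0.39), NQO1 (-0.05 ± 0.17), MT2A (0.47 ± 0.32), MT1X (-0.27 ± 0.29), TFRC (0.17 ± 0.15), CXCL8 (-0.74 ± 0.27), CDKN1A (-0.39 ± 0.15) and HSPA1A (0.27 ± 0.22) did not differ past the threshold between the high fume effects. CXCL8 did so without high fume 0 h replicate 3 (-0.96, adjusted p = 0.0299) and MT1X without clean air 0 h replicate 1 (-0.63, adjusted p = 0.0346). limma called 894 genes, 511 higher and 383 lower. The count was 1815 without clean air 0 h replicate 1 and 2018 with that replicate as the lone clean air array at 0 h. It was 538 without high fume 4 h replicate 1, and 527 with the arrays of the compared groups alone.

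For low fume, EGR1 (2.94 ± 0.33), the peptide gene GRP (2.30 ± 0.19), WDR33 (1.91), TRIM16L (1.72 ± 0.54) and RBM43 (1.67, detected on 2 of 3 low fume arrays at 0 h) had a higher effect at 4 h than at 0 h. RPPH1, the RNA of ribonuclease P (-2.23 ± 0.35), TPD52L1 (-2.19), NPAS4 (-2.14 as fitted), LAMP5 (-2.10 ± 0.15) and DIO2 (-2.01) had a lower one. NPAS4 was detected on 0 of 3 low fume arrays at 4 h and on 2 of 3 clean air arrays at each time. With the low fume set at 4 h at its lowest detected signals its difference was -1.78, so -2.14 and the place among the largest changes are not exact. HMOX1 (-1.14 ± 0.39, adjusted p = 0.0495) and TFRC (0.56 ± 0.15, adjusted p = 0.0148) passed as well. NQO1 (-0.46 ± 0.17), MT2A (-0.12 ± 0.32), MT1X (-0.60 ± 0.29), CXCL8 (-0.01 ± 0.27), CDKN1A (0.23 ± 0.15), HSPA1A (0.60 ± 0.22) and DDIT3 (0.30 ± 0.32) did not. HMOX1 lost its call without any 1 of 9 of the 12 arrays (adjusted p from 0.0543 to 0.156), and TRIM16L without 7 (0.0523 to 0.114). TFRC lost it without clean air 0 h replicate 2 (0.47, adjusted p = 0.0503). NQO1 passed without that array or clean air 4 h replicate 1 (adjusted p = 0.0242 and 0.0347). MT1X (-0.96, adjusted p = 0.00106) and HSPA1A (0.64, adjusted p = 0.0401) passed without clean air 0 h replicate 1. With it as the lone clean air array NPAS4 (-0.74), HMOX1 (-0.73) and TFRC (0.34) lost their calls (adjusted p from 0.0904 to 0.291).

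Of the lists, the cholesterol list had 7 of 18 members with a lower low fume effect at 4 h than at 0 h (10 adjusted over the list alone), with a camera adjusted p = 2.1e-05 (0.256 estimated). The heat shock list had 7 of 20 members with a higher one (9 adjusted over the list alone), with a camera adjusted p = 0.000501 (0.405 estimated). The oxidative phosphorylation list had 2 of 19 with a lower one (4 adjusted over the list alone), with a camera adjusted p = 0.00547 (0.256 estimated). This call ended without clean air 0 h replicate 1 (camera adjusted p = 0.061). limma called 1757 genes, 983 higher and 774 lower. The count was 3423 without clean air 0 h replicate 1, 994 without replicate 2, 1155 without replicate 3, and 950 with replicate 1 as the lone clean air array at 0 h. It was 1119 without low fume 0 h replicate 3, 909 without clean air 4 h replicate 1, and 745 with the arrays of the compared groups alone.

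For clean air, 0 genes differed in effect between 4 h and 0 h by limma, against 661 at an unadjusted p under 0.05. The count stayed at 0 without any 1 array, and was 2235 with replicate 1 as the lone clean air array at 0 h. RFTN1 (-0.76 ± 0.14, adjusted p = 0.214 as fitted), PLEKHH1 (0.84), SAMD1 (-0.82), FAM8A1 (-0.56) and VKORC1L1 (0.56) had the smallest p and did not pass. RFTN1 was detected on 0 of 3 unexposed arrays of the 0 h chip and 2 of 3 of the 4 h chip, and stood at -0.49 with the former at their lowest detected signals. Camera gave adjusted p = 0.00015 for the ATF4 list, 0.000949 for the immediate early list, 0.00925 for the endoplasmic reticulum list and 0.0386 for the airway epithelial and mucin list. For each, limma called 0 members, over all genes and adjusted over the list alone, and adjusted p = 0.566 with an estimated correlation. Without clean air 0 h replicate 1 the camera values became 0.349, 0.794, 0.598 and 0.349.

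Unexposed cells on the chip of the 4 h groups were compared with those on the chip of the 0 h groups to measure what differed between chips. NBPF9 (0.98 ± 0.19), NBPF10 (0.94), STIM1 (0.80), MIX23 (0.80, detected on 1 of 3 arrays of the 0 h chip), GATAD2B (0.71 ± 0.13), YWHAE (0.59), BANF1 (0.52) and INO80E (0.50) were higher. RNF25 (-0.69 ± 0.12) and KRR1 (-0.51) were lower. These were the 10 genes that limma called, with adjusted p between 0.0334 and 0.0444, against 1046 at an unadjusted p under 0.05. Unexposed replicates 4, 5 and 6 resembled replicates 1, 2 and 3 in order. With these pairs as a block limma called 23 genes, these 10 among them. All 10 unpaired calls ended without unexposed replicate 1, 4 or 5, 9 without replicate 2, 6 without replicate 3 and 2 without replicate 6 (adjusted p from 0.061 to 0.279). The limma count was 0 without replicate 1, 4 or 5, 1 without replicate 2 and 23 without replicate 6.

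Across genes, the changes with high and low fume at 4 h had a Pearson r of 0.85 (Spearman rho 0.78). In both, 567 genes were higher and 706 lower (97.8 and 98.98 by chance), and 0 were called in opposite directions. At 0 h r was 0.54 (rho 0.55), with 595 higher and 768 lower in both (187 and 255 by chance). Another 49 were higher with high and lower with low fume, and 21 the reverse. Each of these pairs shares its clean air arrays, which the chance counts ignore. Their covariance was 0.129 at 4 h and 0.0878 at 0 h, where simulated groups without any change, with the spread of each set, gave 0.0148 and 0.0332 from this sharing alone. Without shared arrays, r between 0 h and 4 h was 0.55 (rho 0.45) for high fume and 0.22 (rho 0.21) for low fume. It was 0.89 (rho 0.85) for clean air against unexposed cells, where 2053 genes were higher and 1827 lower at both times with 634 and 486 shared by chance. With clean air 0 h replicate 1 as the lone clean air array at 0 h these 3 values were 0.237, -0.0248 and 0.657. Between the fume changes and those of clean air from unexposed cells r was -0.15 and -0.22 for high fume and -0.0040 and -0.28 for low fume at 0 h and 4 h. The covariances were -0.0372 and -0.0481, and -0.00084 and -0.0608, where the sharing alone gave -0.0332 at 0 h and -0.0148 at 4 h. Genes are not independent replicates, and no p is given for these values.

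Of the 20 fixed lists, 7 were called in none of the 12 comparisons. Iron homeostasis (12 members measured) had a lowest camera adjusted p = 0.156, with 1 higher and 0 lower for the difference of the high fume effects. Interferon-stimulated genes (19 members) reached 0.123, with 2 higher and 4 lower in clean air at 4 h. Aryl hydrocarbon receptor targets (4 members) reached 0.0774, with 0 higher and 2 lower with low fume at 4 h. The osmotic response (5 members) reached 0.175, with 3 higher and 0 lower in clean air at 0 h. The circadian clock (14 members) reached 0.0866, with 1 higher and 0 lower with high fume at 4 h. Apoptosis regulators (16 members) reached 0.265, with 5 higher and 2 lower in clean air at 0 h. Markers of other cell types (4 members) reached 0.0728, with 2 higher and 0 lower with low fume at 0 h. Of the 240 tests of a list in a comparison, 49 were called with the preset correlation and 0 with an estimated one. The median, the mean and the test differed in sign in 28, of which 0 were called.

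The list of markers of other cell types was fixed, and its members are named, although it was not called, after their values were seen. In clean air against unexposed cells CD14 rose by 1.46 ± 0.24 at 0 h and by 1.07 ± 0.24 at 4 h (detected on 2 of 3 unexposed arrays). THY1, a marker of fibroblasts, rose by 1.18 ± 0.10 and 0.96 ± 0.10. PDGFRB, a receptor gene of stromal cells, fell by 1.01 ± 0.18 at 0 h (detected on 1 of 3 clean air arrays). At 4 h, not well above background in clean air, it was at least 1.45-fold lower. The macrophage marker CD68 rose by 0.89 ± 0.32 at 4 h. With high fume CD14 rose by 0.79 ± 0.24 and THY1 by 0.29 ± 0.10 at 0 h. At 4 h CD14 rose by 1.30 ± 0.24 and CD68 fell by 1.42 ± 0.32. With low fume THY1 rose by 0.28 ± 0.10 at 0 h and 0.31 ± 0.10 at 4 h, beside CD14 at 0 h. CD68 fell by 1.40 ± 0.32 at 4 h, and PDGFRB, not well above background in clean air, was at least 1.14-fold higher. The low fume effect on CD68 was lower at 4 h than at 0 h (-1.47 ± 0.45). The adjusted p of these calls was at most 0.0423. CD14 with high fume at 0 h did not pass without clean air replicate 2 or 3 (adjusted p = 0.123 and 0.0697). With replicate 1 as the lone clean air array CD14 and THY1 lost their calls with both fumes at 0 h (adjusted p from 0.248 to 0.982). THY1 did not pass without any 1 of 4 arrays for high fume at 0 h, 5 for low fume at 0 h and 4 for low fume at 4 h (adjusted p from 0.0534 to 0.187). PDGFRB with low fume at 4 h lost its call without 4 of 6 arrays, CD68 in clean air at 4 h without 3, and the difference of the low fume effects on CD68 without 6 of 12 (adjusted p from 0.0564 to 0.139).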

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

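The tests of the array labelled clean air 0 h replicate 1, of small nuclear RNAs and of likeness between unexposed arrays were chosen only after the results were seen, while the counts over other splits of the arrays were planned. The genes and lists in the next 3 paragraphs stood out because their effects at 4 h and at 0 h differed by a test of the difference itself. Time and chip coincide in this design, so a chip effect that differs between groups would enter these differences as well.

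For high fume, the effect at 4 h less that at 0 h was 2.86 as fitted for ARL14 (not detected with high fume at 0 h, and 2.41 with that set at its lowest detected signals), 2.04 for EGR1, 1.93 for H2BC26, 1.87 for KLHL24, 1.80 for ENPP5 and 1.36 for DDIT3. It was -1.72 for LIG1, -1.68 for PLK1, -1.67 for AURKB, -1.66 for TACC3 and -1.57 for ZWINT. Of the lists, camera gave an adjusted p = 5.3e-24 for the cell cycle (median -0.95), 0.00021 for cholesterol biosynthesis (-0.40), 0.00337 for oxidative phosphorylation (-0.32) and 0.00419 for ATF4 (0.37). With an estimated correlation these were 0.127, 0.256, 0.256 and 0.688, and the ATF4 call ended without clean air 0 h replicate 1 (adjusted p = 0.589, median 0.15). limma called 894 genes in all. Of 100 splits drawn, the real one included, 7 called as many. These splits test for no effect at all, not for equal effects, so they cannot decide on chance for this count. The highest other split called 2443. It exchanged clean air 0 h replicates 2 and 3 with high fume 0 h replicates 1 and 3. This partly reverses the effect at 0 h and moves the difference of the effects towards their sum, and no test parted that from the unlike clean air arrays.

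For low fume, the effect at 4 h less that at 0 h was 2.94 for EGR1, 2.30 for GRP, 1.91 for WDR33, 1.72 for TRIM16L, 1.67 for RBM43 and 0.56 for TFRC. It was -2.23 for RPPH1, -2.19 for TPD52L1, -2.14 as fitted for NPAS4 (not detected with low fume at 4 h, and -1.78 with that set at its lowest detected signals), -2.10 for LAMP5, -2.01 for DIO2, -1.47 for CD68 and -1.14 for HMOX1. Camera gave an adjusted p = 0.000501 for heat shock (median 0.43), 2.1e-05 for cholesterol biosynthesis (-0.51) and 0.00547 for oxidative phosphorylation (-0.34). With an estimated correlation these were 0.405, 0.256 and 0.256, and the oxidative phosphorylation call ended without clean air 0 h replicate 1 (adjusted p = 0.061). limma called 1757 genes in all. Of 100 splits drawn, the real one included, 2 called as many. Splits test for no effect at all, not for equal effects, so chance stays open. The highest other split called 3428 genes and exchanged all clean air and low fume labels at 0 h, which turns the difference of the effects into their sum.

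For clean air, camera gave an adjusted p = 0.00015 for ATF4 (median -0.40), 0.000949 for the immediate early list (-0.30), 0.00925 for the endoplasmic reticulum list (-0.18) and 0.0386 for the airway epithelial and mucin list (-0.30). Each was 0.566 with an estimated correlation. Without clean air 0 h replicate 1 they were 0.349, 0.794, 0.598 and 0.349, and the medians of ATF4 and the immediate early list moved to -0.0607 and -0.0468. limma called 0 genes in all, against 661 at an unadjusted p under 0.05, so all 100 splits called as many. The highest other split, which exchanged unexposed replicates 4 and 6 with clean air 4 h replicates 2 and 3, called 4225 genes and thus follows the difference between clean air and unexposed cells. The STC2 value of unexposed replicate 6 (log2 of 5.45, with the nearest at 5.88) lay far from the other unexposed arrays. Its gap was 0.717 of their range, over the 95% critical value of Dixon for 6 arrays. This was 1 of 59 values tested, and chance gives about 1 in 20.

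Clean air 0 h replicate 1 differed by 0.516 to 0.537 from replicates 2 and 3, the nearest to clean air 4 h replicates 2 and 3 (0.223 and 0.233). A failed hybridisation was argued against, since replicate 1 lay 0.302 from its nearest array of another set, within the 0.21 to 0.342 found inside the other sets. RNA of clean air 4 h cultures under the labels of replicates 2 and 3 stayed open. A time score over 856 genes moving with time in both fume groups (0 at 0 h, 1 at 4 h) could not decide. Replicates 2 and 3 averaged 0.729 and the 3 clean air 4 h arrays lay at 0.834 to 0.891. Unexposed arrays, without such a time, lay at 0.648 to 0.723. Low fume RNA under the label of replicate 1 remained a candidate. Replicate 1 lay at 0.0514 between low (0) and high fume (1) at 0 h, against 0.37 to 0.44 for replicates 2 and 3. Its time score of 0.245 lay outside the -0.0457 to 0.0509 of the fume 0 h arrays, but these set the score. No biological explanation was tested, which of the 3 arrays are out of place stays open, and the means of high and low fume at 0 h include none of them, although they enter the variance of every fit.

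The 12 genes with small nuclear RNA symbols had a median of 2.27 for high fume against clean air at 4 h, with 11 called higher and 0 lower (camera adjusted p = 2.24e-10, and 0.0755 with an estimated correlation). The normalization was argued against as the whole cause, since the lowest median over the normalizations tried was 1.96. Probes shared by near-identical copies of U1 were argued against in the same way, since the 8 genes outside the U1 family had a median of 1.49. More short RNA kept in the extraction was argued against, since 126 small nucleolar, small Cajal body and other short RNAs had a median of -0.21 and a 75th percentile of 0.13, below the 25th percentile of 1.33 of the small nuclear RNAs, although the 14 small Cajal body RNAs among them rose (median 0.52, 6 higher and 1 lower, adjusted p = 0.031, and 0.225 with an estimated correlation). A rise of these RNAs in the exposed cells may remain, as a hypothesis found and tested on the same data, and not shown to be of fume alone, since they were higher in clean air than in unexposed cells too (medians of 1.37 at 0 h, 0.73 without clean air 0 h replicate 1, which ended the call with adjusted p = 0.0863, and 1.17 at 4 h, with 8 called at each time, and 0.722 and 0.548 with an estimated correlation).

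Unexposed replicates 1, 2 and 3 of the 0 h chip and 4, 5 and 6 of the 4 h chip resembled each other in order, with correlations of their deviations from the mean of their set of 0.27, 0.29 and 0.56. The mean of 0.38 was as high in 1 of the 6 pairings, this one, and 0.34 in the next. The same RNA hybridised on both chips and separate cultures cannot be told apart, since 6 pairings are too few, and no biological explanation was tested.

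For the comparisons of 3 arrays with 3, 10 splits exist, so the share that calls as many genes is never under 0.1. In each of them 1 split, the real one, called as many. The real counts and the highest other counts were 3667 and 542 for high fume, 2822 and 1804 for low fume and 2433 and 0 for high against low fume at 0 h. They were 2042 and 0, 2265 and 1, and 40 and 1 for the same comparisons at 4 h. For clean air against unexposed cells they were 5188 and 469 at 0 h and 5052 and 1 at 4 h, and for the unexposed arrays of the chips 10 and 1. The split with 1804 exchanged clean air replicate 1 with low fume replicate 1, and those with 542 and 469 also moved clean air replicate 1.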

How the results depend on the processing

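The fits with clean air 0 h replicate 1 as the lone clean air array at 0 h, the lists without that array, the correlations under other settings and the block across chips were chosen only after the data were seen, and the other alternatives were planned. A count that moved lay outside 1.5 times the reported one, and the cause was not tested unless an alternative's construction shows it.

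Of 343 reported gene values, 341 kept direction and side of the threshold with normalization per chip and with all probes counted, 330 with the authors' values and without background correction, 326 with 75th percentile scaling, 324 without the filter on dim probes, and 256 of 256 that could be tested with probes detected on all arrays. Array weights kept 328 (1 lost, 14 gained a call), the 1.5-fold minimum 320, the replicate block 323, the stricter adjusted p 287 and the compared groups alone 283 (55 lost, 5 gained). None of these reversed a value. Leaving out 1 array kept 2067 of 2322 values, ended 244 calls, added 11 and reversed 0. With unexposed cells as the control 111 of 151 were kept and 20 reversed, and with replicate 1 alone 99 of 155 were kept and 8 reversed.

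Counts moved without background correction to 66 for high against low fume at 4 h and 23 between the chips, and with 75th percentile scaling to 4 between the chips, of which 1 was higher. High against low fume at 4 h had 24 genes with the authors' values and 26 with probes detected on all arrays, where the chips differed in 20. Counts fell with the 1.5-fold minimum, by its construction, to 1790 and 1231 for high and low fume at 0 h, 1044 and 1033 at 4 h, 1318 for high against low fume at 0 h, and 2827 and 2825 for clean air at 0 h and 4 h. Likewise an adjusted p under 0.01 gave 2217 and 1225 for high and low fume at 0 h, 999 and 1041 at 4 h, 1270 and 5 for high against low fume at 0 h and 4 h, 330 and 497 for the differences of the high and low fume effects, and 0 between the chips. With the compared groups alone, fewer arrays enter, and their own spread is not diluted by other sets. High and low fume at 0 h had 2088 and 0, clean air at 0 h 3010, the differences of effects 527 and 745, and the chips 0. High against low fume at 4 h rose to 172. With array weights high and low fume at 0 h had 6569 and 6127, high fume at 4 h 3200, high against low fume 4579 and 897 at 0 h and 4 h, the differences of effects 2934 and 4265, and the chips 83. A block for the replicate number within a chip left 0 between the chips (adjusted p of the 10 genes from 0.0639 to 0.0916, with the same changes), and a block for the pairs of unexposed arrays across chips gave 23 and changed no call of the clean air difference. With normalization per chip 8 genes were higher and 5 lower between the chips. All counts of 0 are from limma, against unadjusted p under 0.05 in the fit of all arrays for 1046 genes between the chips and 4353 for low fume at 0 h. The replicate numbers did not pair the arrays within a chip: 36 pairs with the same number on a chip had correlations of deviations from -0.32 to 0.25, with a median of 0.018 against -0.0037 for different numbers, 8 pairs were over 0.1, and 12 of 24 arrays correlated best with their own number.

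Leaving out 1 array gave 2777 to 4779 genes for high fume and 995 to 4705 for low fume at 0 h, 1150 to 1876 and 1101 to 2169 at 4 h, and 1648 to 1963 and 2 to 32 for high against low fume at 0 h and 4 h. It gave 4554 to 5159 and 4145 to 4667 for clean air, 538 to 1815, 909 to 3423 and 0 to 0 for the differences of the high fume, low fume and clean air effects, and 0 to 23 between the chips. The highest counts at 0 h against clean air, and of the fume differences, came without clean air 0 h replicate 1.

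With unexposed cells as the control, high and low fume gave 6012 and 5949 genes at 0 h and 5464 and 5435 at 4 h, which by construction includes the response to the exposure system. Reversed were, for high fume at 0 h, CAMKV (0.72), P2RX2 (0.035), HSPA6 (0.23), HSPA1A (0.092), MT1E (0.72) and MT1F (3.36). For low fume at 0 h they were IMMP2L (-0.16), PLAAT4 (-0.25), CAMKV (1.02), CAV1 (0.76), TFRC (0.135) and HSPA1A (0.34). At 4 h they were CAMKV (1.86), TAGLN (1.56) and TKT (-0.42) for high fume and CAMKV (2.17), TAGLN (1.765), MT1E (0.25), PDGFRB (-0.35) and HMGCS1 (0.50) for low fume.

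With replicate 1 as the lone clean air array at 0 h, low fume at 0 h gave 5 genes and the differences of the high fume, low fume and clean air effects 2018, 950 and 2235. SLC30A1 (-0.22) and CD14 (-0.011) reversed for high fume, and for low fume MT1X (-0.14), SLC39A10 (0.018), SLC30A1 (-0.39), STC2 (-0.42), DDIT4 (-0.26) and NR4A2 (-0.18) did. So did the ATF4 and immediate early lists for low fume (adjusted p of 0.0017 and 0.0821), and the correlation of the low fume changes between times (-0.0248), while those of high fume and clean air moved to 0.237 and 0.657.

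Of 49 list calls, 0 passed camera with an estimated correlation, 48 stood without background correction, 49 with 75th percentile scaling, 49 with the block and 42 without clean air 0 h replicate 1. With that array as the lone clean air array at 0 h 44 stood, 3 ended and 2 reversed, among 73 calls in all. No scaling moved the median of all genes by over 0.1. Signal over background limits what could be seen. Of the probes, 39.7% to 43.0% were detected per array, and a change under that level, as for CYP1A1, was not measured.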

Other observations

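The gene classes below were tested only after the data were seen, while the criteria for the histone and S phase tests were written before those values were computed. Of the 12 genes classed by symbol alone as small nuclear RNAs, 10 were higher and 0 lower with high fume at 0 h (median 1.83, camera adjusted p = 3.86e-06, and 0.154 estimated), and RNU105C stood at -0.13. Clean air 0 h replicate 1 moved with this class. Its median from the mean of all arrays was 0.74, against -1.04 and -1.07 in replicates 2 and 3. Without it the change was 2.44 (11 higher), and with it as the lone clean air array at 0 h 0.64 (1 higher, adjusted p = 0.0322). The small Cajal body RNAs, which guide the modification of spliceosomal RNAs, were higher with high fume at 0 h. Of 14 genes, 8 were called higher and 0 lower against clean air (median 0.70, camera adjusted p = 0.000273, and 0.0937 estimated). Without replicate 1 and with it alone the median was 0.63 and 0.66 (adjusted p = 0.00722 and 0.000291). Against low fume 8 were higher and 0 lower (median 0.62, adjusted p = 4.04e-05, and 0.0853 estimated). Small nucleolar RNAs were lower at 4 h. Of 103 genes, 36 were lower and 6 higher with high fume (median -0.26, adjusted p = 2.74e-06, and 0.267 estimated).

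Of 341 zinc finger genes, 120 were lower and 15 higher with high fume at 0 h (median -0.31, camera adjusted p = 2.96e-08, and 0.0051 estimated). With low fume 101 were lower and 13 higher (median -0.20, adjusted p = 1.8e-05, and 0.0304 estimated). Without replicate 1 and with it alone the medians were -0.36 and -0.18 for high and -0.26 and -0.13 for low fume (adjusted p at most 0.000564). For high against low fume 38 were lower and 11 higher, with a median of -0.04 at percentile 2.28 of 10000 random lists matched on mean expression, and camera did not call the class (adjusted p = 0.0547).

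Replication-dependent histone genes, whose messages end without a poly(A) tail in dividing cells, were higher with high fume at 4 h. Of 50 genes, 18 were called higher and 0 lower (median 0.29, camera adjusted p = 1.53e-07, and 0.0599 estimated). Against low fume at 4 h 6 were higher and 0 lower (median 0.42, adjusted p = 2.61e-21, and 0.000431 estimated). A hypothesis was a rise of messages not ended by polyadenylation, tested against 7 polyadenylated histone variants. How the labelling copied messages without a poly(A) tail was not tested. The medians differed by 0.15 for high fume against clean air at 4 h (exact permutation p = 0.41, adjusted p = 0.862 over 6 comparisons), and by 0.29 for high against low fume at 4 h (p = 0.0197, adjusted p = 0.118). The criterion set beforehand counted a p of 0.05 or more against the hypothesis and was wrong, since a p that misses the threshold excludes nothing. With 7 genes in the smaller class this explanation cannot be told apart from its absence. The other hypothesis was more cells in S phase. The 13 S phase genes of the cell cycle list had a median of 0.22 for high fume against clean air at 4 h, at percentile 97.9 of matched random lists, with 5 called higher and 0 lower. The classes did not keep step elsewhere. For high against low fume at 4 h, with its histone median of 0.42 but fewer histones called, the S phase genes had a median of 0.13 (percentile 98.9) and 0 called. With high fume at 0 h they had a median of 1.01 and 11 called, while the histones had 0.22 (16 higher, 3 lower). More cells in S phase thus stays open for high fume at 4 h, in a test on the data in which the pattern was found, and was not shown to set the size of the histone changes.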
